A study of Homo sapiens with 6 samples.

How the data were processed

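RNA from 6 samples of A549 cells, an established human lung adenocarcinoma line, was hybridised to Affymetrix whole-transcript arrays. The labels give 3 groups of 2 arrays each: vehicle, Comp.2 and Comp.4. Per the labels' protocols, treatment began a day after plating, the dose was 2 µM, and RNA was extracted with a column kit 2 days later. Biotinylated cDNA was made with the WT PLUS kit, per the labels' protocols. The treatment labels of the treated samples give 2 µM for Comp.2 and for Comp.4.

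The deposited table holds 1 log2 value per probe set and array for 53617 probe sets, and these log2 values were made by the authors with RMA (background correction, quantile normalization and summary of probes), per the submitters' processing notes. Those notes also name Affymetrix Expression Console 1.3.1 and Transcriptome Analysis Console 2.0, and do not say which step each ran. Scanner files, scan dates and detection calls were not used here. The medians of the 6 arrays lay between 4.55 and 4.56, so the scale of the arrays had already been made equal, and a change shared by most transcripts could not be seen in these values. RMA values carry a floor set by background, which makes fold changes of dim probe sets too small.

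Gene names came from the platform annotation paired with the probe sets. Of the 53617 probe sets, 23871 had 1 gene symbol, 1842 had several and 27904 were unnamed here. The Entrez number of 22569 of the single-symbol probe sets was found in a RefSeq gene table of GRCh38.p14, which updated 90 symbols. That table served for names and gene classes alone, and no coordinates were taken from it. Probe sets with several symbols or none entered no gene comparison. Where a gene had more than 1 probe set (632 genes), the probe set with the highest mean over all arrays stood for it, which left 22395 genes, 17062 of them protein-coding.

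Differences were tested with limma 3.58.1 in R 4.3.3. A linear model with a mean per group was fitted to all 6 arrays, so that the 3 groups shared 1 estimate of the spread, with 3 residual and 3.71 prior degrees of freedom. The 3 contrasts were Comp.2 against vehicle, Comp.4 against vehicle and Comp.4 against Comp.2. P-values are two-sided and were adjusted by the Benjamini-Hochberg method over the 22395 genes within a contrast, with a threshold of 0.05. Standard errors (SE) and 95% intervals come from the moderated variance. A permutation test of 2 arrays against 2 cannot go below a two-sided p of 0.333, so none was run.

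A set of 32 gene lists was written from textbook knowledge, covering cell cycle, p53, apoptosis, histone acetylation, stress responses, metabolism, signalling and lineage, and markers of fibroblasts, endothelium and leukocytes. Of 767 symbols written, 630 distinct genes were measured, and 24 genes stood in more than 1 list. For each list, members past the threshold were counted over all genes tested and adjusted over the list alone. The list as a whole was compared with all other genes by limma's camera with a preset correlation of 0.01, adjusted over the 32 lists. That setting takes the members of a list as nearly independent, so its p-values rest on genes rather than arrays and may be far too small. Camera with an estimated correlation and limma's fry were run beside it. With an estimated correlation camera rests on the 3 residual degrees of freedom, which leaves it little power after adjustment over 32 lists.

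The genes named per contrast were the 10 largest rises and 10 largest falls past the threshold whose arrays did not overlap between groups, up to 3 members of each list past the threshold with the largest changes, and the acetyltransferase genes EP300 and CREBBP. Where fewer than 10 passed, the largest changes that did not pass were taken from the brighter genes, meaning those with a mean over the 6 arrays above the median gene. The first part of the rule skipped symbols with set prefixes or endings, those of most small RNA, LINC, microRNA and antisense genes; 5S-named genes with the prefix RN5S were not on that list and were kept. Further genes given as examples of a list, of a class of RNA or of a count were chosen after their values were seen. The groups, the model, the lists, the naming rule and all alternatives but 1 (protein-coding genes only) were set before the data were examined.

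Comparisons of both compounds share the vehicle arrays. The covariance, correlation and overlap of their fold changes were therefore set beside 100 simulations of unchanged groups against shared controls. The vehicle arrays were too few to be split. For genes that differed between the compounds, the sum of both fold changes was also tested one-sided with the moderated variance, adjusted within the protein-coding and the long noncoding or pseudogene set. Its estimate is independent of the difference that picked the genes, while the variance is shared, which makes its p-values somewhat too small. The Comp.4 change of the protein-coding genes was also tested one-sided in the direction of the difference, at 0.05 times the share of protein-coding genes picked (0.000126).

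The alternatives were a replicate block, each array left out in turn, a fit of only the 2 groups compared, a variance trend, a robust variance, array weights, another quantile normalization, median centring, brighter genes only, the mean of a gene's probe sets, all probe sets, an adjusted p of 0.10, and cutoffs on fold size. The fitting steps were tested on simulated values for the 22395 genes with 200 genes changed. In the Comp.2 contrast, 65.7% of planted log2 changes of 0.5 and 100% of those of 1 were called; in the Comp.4 contrast 64.2% and 98.5%, and between the compounds 70.1% and 100%. Unchanged genes called numbered 11, 7 and 15 in these simulations. The simulated noise was normal with the moderated variances, so these shares need not hold for the measured arrays. There the smallest changes called against vehicle were 0.62 (RN5S70) under Comp.2 and -0.61 (SERPINB9) under Comp.4. Medians of RNA classes have 95% bootstrap intervals from 10000 resamples of genes, and genes are not independent replicates. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.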

Results

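Transcript levels were compared in A549 cells 2 days after treatment with vehicle or with 2 µM of Comp.2 or Comp.4. The series title calls these code-named compounds inhibitors of histone acetyltransferases that recognise DNA sequence, and the stated aim was to examine how each altered gene expression. Each of the 3 groups held 2 arrays. Deposited log2 levels ran from 1.80 to 13.26. Across probe sets, Pearson's r was 0.994 between the vehicle arrays and 0.992 within either compound, against 0.989 to 0.992 between groups. The SD of the log2 difference was 0.158 to 0.183 within groups and 0.196 to 0.223 between them. On the first principal component (32.2% of the variance) the Comp.4 arrays lay at 17.1 and 14.1, and the other 4 arrays between -9.92 and -4.33. The second component (24.3%) set vehicle, at 10.9 and 10.5, apart from Comp.2, at -11.0 and -14.5. The number of arrays limits the precision. The labels do not say that replicates were separate cultures, so p-values of single genes measure only the spread between these samples, which may be technical. Those of camera with the preset correlation rest on an assumed near-independence of genes.

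The first comparison asked which transcripts Comp.2 altered against vehicle. Of 28 measured p53 target genes 10 rose, and of 25 genes of the integrated stress and unfolded protein responses 4 fell, while no member of the first list fell and none of the second rose. SPATA18, a p53-induced gene acting in mitochondrial quality control, rose from 5.52 ± 0.09 to 7.09 ± 0.05 (log2, mean ± SD, n = 2 arrays each), a 2.98-fold change (log2 1.57, SE 0.08). CDKN1A, which encodes a cyclin-dependent kinase inhibitor, rose 2.28-fold, from 6.16 ± 0.11 to 7.35 ± 0.18. CHAC1, which encodes an enzyme that degrades glutathione, had the largest fall, 3.64-fold, from 7.97 ± 0.08 to 6.10 ± 0.18. ASNS, the asparagine synthetase gene, fell 2.01-fold, from 8.41 ± 0.05 to 7.40 ± 0.13.

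Of 22395 genes, 30 were higher under Comp.2 (24 of them protein-coding) and 14 lower (11 protein-coding). The change was at least 2-fold for 7 of the higher and 5 of the lower genes. Other large rises were those of EDA2R, a receptor of the TNF receptor superfamily (log2 1.34, SE 0.08, adjusted p = 0.00603), the lipid transporter gene ABCA12 (1.28, SE 0.13), the sulfatase gene SULF2 (1.09, SE 0.08), and MDM2, which encodes the ubiquitin ligase of p53 (0.98, SE 0.08). The long noncoding RNAs GACAT2 (1.05) and PURPL (0.97) and the stress-response gene SESN1 (0.93) also rose. UIMC1 rose by 0.95 on its brighter probe set, while its other probe set had -0.18, so its direction is unsettled. Among the falls, ULBP1, which encodes a ligand of a natural killer cell receptor, had log2 -1.23 (SE 0.11). STC2, a secreted glycoprotein gene, had -1.23 (SE 0.08). CARS1, the cysteinyl-tRNA synthetase gene, fell by 0.93, ALDH1L2 of mitochondrial folate metabolism by 0.89 and PSAT1 of serine synthesis by 0.82. The pseudogene GUSBP3 (-1.40), the noncoding NDUFA6-DT (-0.76) and the taste receptor gene TAS2R19 (-0.74, at low signal) also fell.

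**Figure D1:**
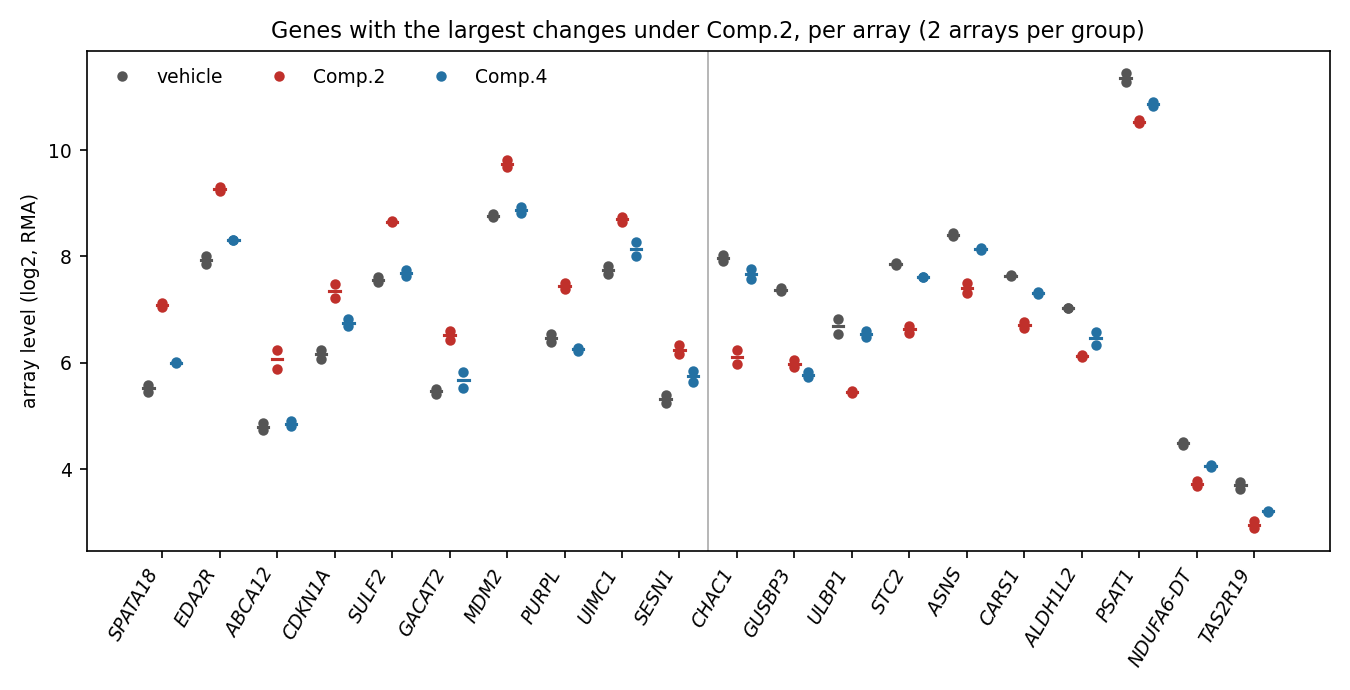
Array levels (y axis, log2 RMA units) of the 10 largest rises and 10 largest falls under Comp.2 that the naming rule took (x axis, rises left of the grey line). Each dot is 1 array and each bar a group mean; SPATA18 stood at 5.52 with vehicle, 6.00 with Comp.4 and 7.09 with Comp.2, and CHAC1 at 7.97, 7.68 and 6.10.

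Of the 28 measured p53 targets, 10 rose under Comp.2, none fell and 18 did not pass; adjusted over the list alone, 24 were higher, and 23 were with a variance trend or among the brighter genes. The median log2 change was 0.63, and 27 of the 28 had a positive fold change. Beside SPATA18, EDA2R, CDKN1A, MDM2 and SESN1, the risers were POLH (0.91) and DDB2 (0.85), both of the response to UV damage, the death receptor gene FAS (0.88), GADD45A (0.64) and PPM1D (0.62). The list test gave an adjusted p of 6.86e-36, and an adjusted p = 0.0599 with an estimated correlation. FAS was the 1 pro-apoptotic gene of 23 measured that rose; BAX, at 0.80, did not pass (adjusted p = 0.0761), and adjusted over the list alone 4 were higher. That list had a median of 0.09 (camera adjusted p = 0.0135; adjusted p = 0.207 with an estimated correlation). None of the 16 anti-apoptotic genes passed.

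Of the 25 measured genes of the integrated stress and unfolded protein responses, 4 fell under Comp.2: CHAC1, ASNS, PSAT1 and PHGDH (-0.69), the last another enzyme of serine synthesis. Adjusted over the list alone, 8 were lower, as were 8 with a variance trend and 6 of 23 among the brighter genes. ATF4, the transcription factor of this response, had -0.42 and did not pass (adjusted p = 0.135), and the chaperone gene HSPA5 had -0.10. The median was -0.10, with a camera adjusted p of 3.2e-07 and an adjusted p = 0.132 with an estimated correlation. None of 15 measured core and linker histone genes passed, of 33 written; 5 were lower with a variance trend, and 3 of 11 among the brighter genes. Adjusted over the list alone 8 were lower, such as H1-5 (-0.62) and H2BC3 (-0.58), and the median was -0.23 (camera adjusted p = 1.13e-05; adjusted p = 0.151 with an estimated correlation). Histone genes have near-identical copies, so single members are uncertain. No member passed among 29 genes of G1/S and DNA replication (median -0.10), 28 of mitosis (-0.08) or 22 MYC targets (-0.13), though these lists passed camera; with an estimated correlation their adjusted p was 0.207, 0.253 and 0.207.

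HSPA4L, a heat shock protein gene, rose by 0.80 as 1 of 14 heat shock genes. In the list of senescence-associated secretion and growth factors, CDKN1A and GDF15 (0.85), a stress-induced cytokine gene, rose and STC2 fell, of 23 measured. CD68, a lysosomal glycoprotein gene used as a macrophage marker, rose by 0.67 as 1 of 11 leukocyte markers, and no marker of fibroblasts (8) or endothelium (9) passed. No histone acetyltransferase or acetyl reader passed among 22 measured (camera adjusted p = 0.709). EP300 had -0.06 (95% interval -0.27 to 0.14) and CREBBP 0.01 (-0.19 to 0.20). No list in any of the 3 contrasts passed with an estimated correlation, a test that has little power here. With the preset correlation 15, 7 and 9 passed, and with fry in one direction 14, 7 and 9.

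Without any 1 of the vehicle or Comp.2 arrays, where fewer residual degrees of freedom remain, limma called no gene, with 932 to 1470 genes higher and 722 to 1036 lower at an unadjusted p under 0.05, against 1396 and 1106 with all arrays. The p53 target median was 0.62 to 0.68 in those fits. Without either Comp.4 array or the Comp.4 group, 9 genes were higher and 5 lower. All 44 called genes kept their sign without any 1 array, which was fixed in advance, since their arrays did not overlap between groups. With all probe sets tested together none passed (2303 and 2459 unadjusted).

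The second comparison asked which transcripts Comp.4 altered against vehicle. Most genes past the threshold were not protein-coding, 10 of the 12 higher and 18 of the 21 lower. This did not hold at an unadjusted p under 0.05. GDF15 rose 1.66-fold, from 9.23 ± 0.0001 to 9.96 ± 0.07 (log2, mean ± SD, n = 2), and SLC51B, a subunit of a bile acid transporter, rose 1.74-fold, from 7.03 ± 0.13 to 7.83 ± 0.001. GUSBP3 fell 3.04-fold, from 7.38 ± 0.04 to 5.78 ± 0.08, and FTX, a long noncoding RNA, 2.09-fold, from 7.08 ± 0.14 to 6.01 ± 0.19. SERPINB9, which encodes an inhibitor of granzyme B, fell 1.52-fold, from 8.14 ± 0.01 to 7.53 ± 0.01.

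Under Comp.4, 12 genes were higher, 2 of them protein-coding (SLC51B and GDF15), and 21 lower, 3 of them protein-coding (SERPINB9, METTL2B and CSNK1G1). At an unadjusted p under 0.05 there were 1935 and 1764. A fit of protein-coding genes alone gave 1627 and 1539 at that level, so most changes there were protein-coding. The 5S-named genes RN5S150 (log2 1.13, SE 0.11), RN5S19 (1.01, SE 0.08) and RN5S199 (0.96, SE 0.10) rose; as near-identical copies they are uncertain as single genes. Other falls were those of the pseudogene WHAMMP1 (-1.07, SE 0.11), the noncoding FAM157B (-0.87, SE 0.09) and METTL2B, a tRNA methyltransferase gene (-0.68, SE 0.08). POLR2J4 (-0.79) and the casein kinase gene CSNK1G1 (-0.63) also fell, but their other probe sets had 0.20 and -0.12. Changes that did not pass were named only from brighter genes whose symbols the rule kept and whose arrays did not overlap between groups. The largest rises among those were RN5S99 (1.03), RN5S132 (0.97), the chemokine gene CCL2 (0.86, adjusted p = 0.105), RN5S85 (0.74) and RAP1GAP (0.71). The largest falls among them were GPR135 (-0.94) and HNRNPA1 (-0.93). Among the 238 small nucleolar and Cajal body RNA genes, 5 rose, such as SNORA38B (0.88) and SCARNA6 (0.75), and 1, SCARNA3, fell (-1.47). The 118 brighter ones had a median of 0.27 (95% bootstrap interval 0.20 to 0.31), with 83.9% above 0, against -0.10 (-0.14 to -0.04) under Comp.2. LINC-named long noncoding RNAs had 5 falls and no rise of 644 measured, LINC01347 the largest (-1.15), though the median over all 644 was 0.03 and over the 80 brighter ones -0.10.

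**Figure D2:**
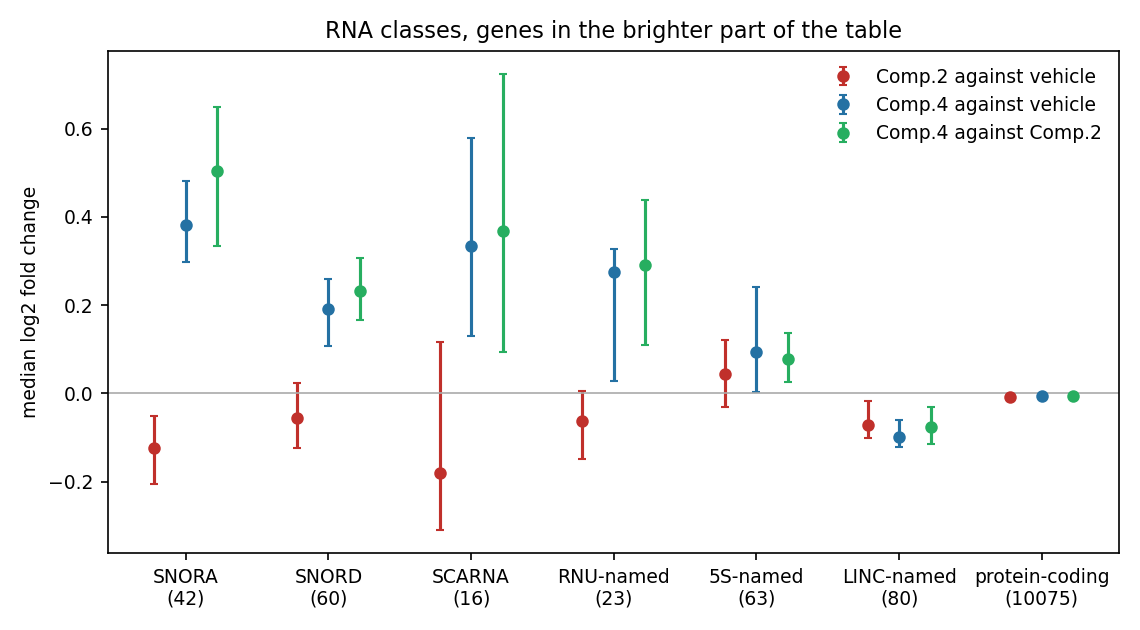
Median log2 fold change (y axis) of genes above the median level over the 6 arrays, in 7 classes (x axis, number of genes in brackets) in the 3 contrasts, with 95% bootstrap intervals over genes as bars. The SNORA class had 0.38 under Comp.4 and -0.12 under Comp.2 against vehicle, while protein-coding genes had medians near 0 in each contrast.

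No p53 target passed under Comp.4, against 7 with a variance trend and 5 among the brighter genes. Adjusted over the list alone 7 of 28 were higher, among them CDKN1A (0.60) and SPATA18 (0.48), and the median was 0.19. As under Comp.2, 27 of the 28 p53 targets had a positive fold change, though the shared vehicle arrays may add to this likeness. That list and the NF-κB targets both had a camera adjusted p of 4.11e-07, with an adjusted p = 0.319 and an adjusted p = 0.266 with an estimated correlation. Of the 25 NF-κB targets none passed, 10 were higher adjusted over the list alone, such as CCL2, the chemokine gene CXCL8 (0.60) and NFKB2 (0.47), and the median was 0.20. The 19 cholesterol synthesis genes had a median of 0.17, with 5 higher adjusted over the list alone, among them INSIG1 (0.38) and IDI1 (0.37); the camera adjusted p was 6.02e-05, and the adjusted p = 0.373 with an estimated correlation.

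The 22 histone acetyltransferases and acetyl readers had a median of -0.15 under Comp.4 and none passed; CREBBP and KAT6B (-0.39) were lower adjusted over the list alone. CREBBP had -0.41 (95% interval -0.61 to -0.22, adjusted p = 0.104) and EP300 -0.31 (-0.51 to -0.11, adjusted p = 0.163). The camera adjusted p of this list was 0.0115, and the adjusted p = 0.373 with an estimated correlation. TGF-β targets (median -0.14, none of 21 past), DNA repair genes (-0.09, none of 22) and genes of G1/S and DNA replication (-0.10, none of 29) also passed camera, each with an adjusted p = 0.373 with an estimated correlation. The stress response list did not pass: its median was 0.02 while its mean was -0.05 and its test direction was down. No fibroblast, endothelial or leukocyte marker passed.

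The Comp.4 gene counts moved with the setting: 488 genes were higher and 738 lower with a variance trend, and 340 and 499 among the brighter genes. In turn, limma called none without any 1 of the 6 arrays (1228 to 1999 higher and 1150 to 1767 lower at an unadjusted p under 0.05), and none when protein-coding genes alone were tested (1627 and 1539). All 33 called genes kept their sign without any 1 array, which was again fixed in advance by arrays that did not overlap between groups.

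**Figure D3:**
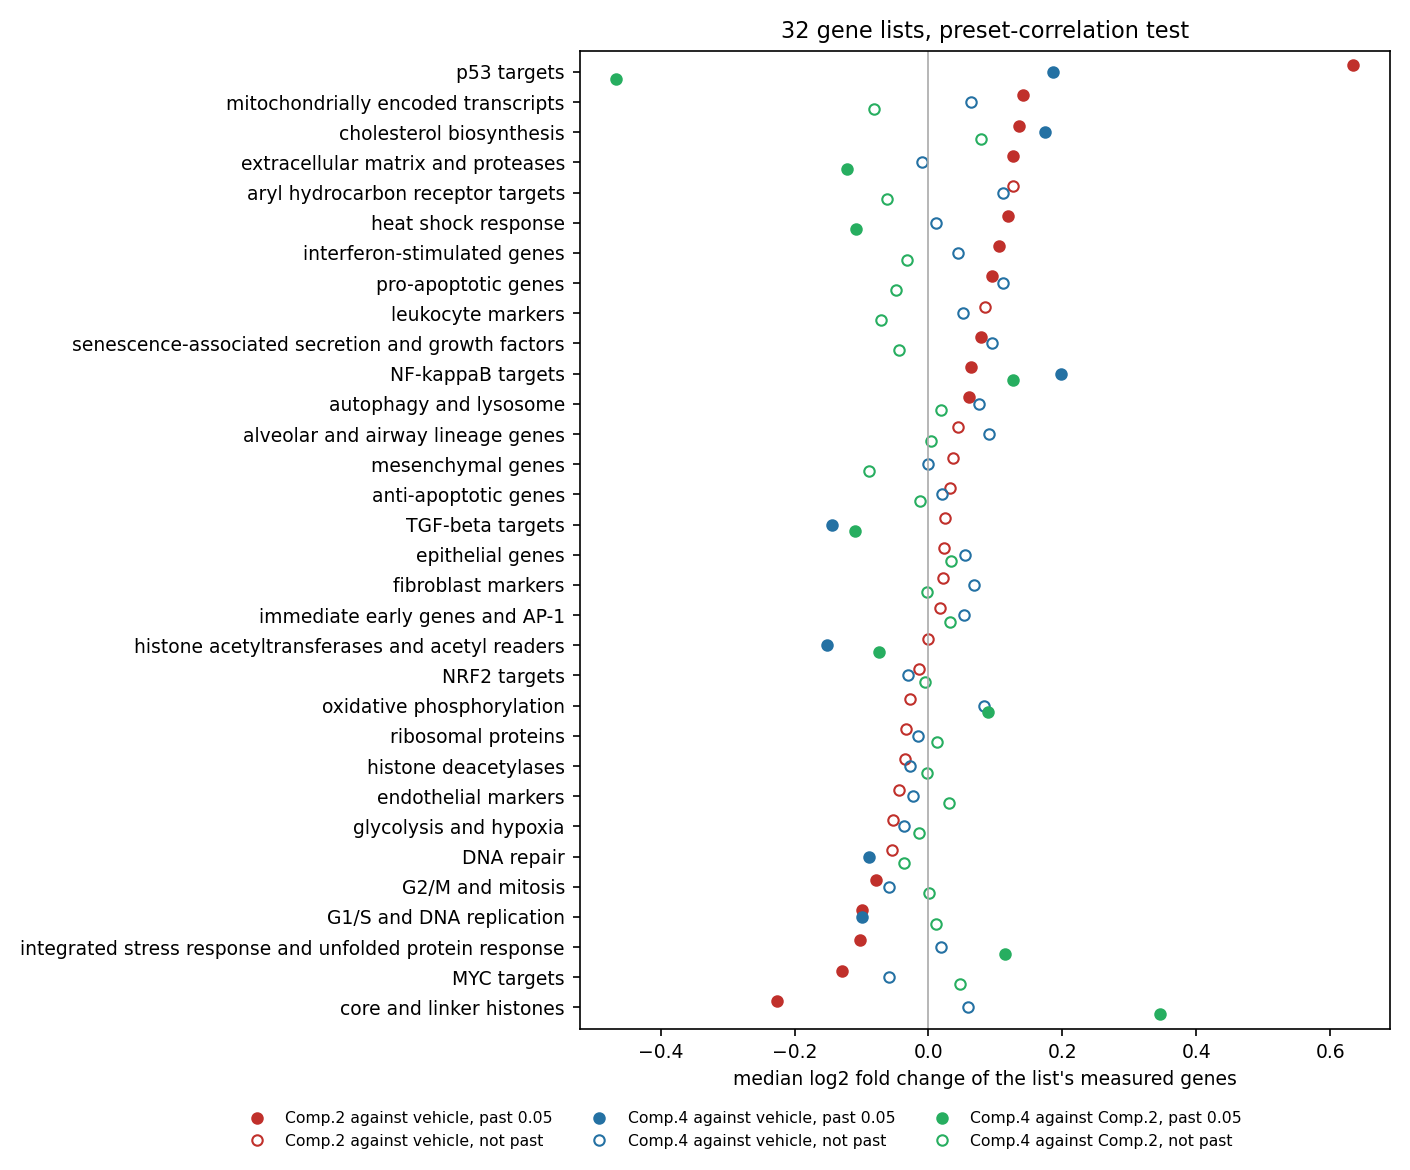
Median log2 fold change (x axis) of each of the 32 gene lists (y axis) in the 3 contrasts; filled circles passed camera with the preset correlation at an adjusted p of 0.05, and open circles did not. The p53 targets had medians of 0.63 under Comp.2 and 0.19 under Comp.4, and core and linker histones -0.23 and 0.06.

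The third comparison set the compounds against each other at the same dose and day. The stress response genes CHAC1 and ASNS and the histone genes H2BC3 and H1-5 were higher, and 5 of 28 p53 targets lower, under Comp.4 than under Comp.2. CHAC1 was 2.97-fold higher under Comp.4, at 7.68 ± 0.13 against 6.10 ± 0.18 (log2, mean ± SD, n = 2), and ASNS 1.67-fold higher, at 8.14 ± 0.03 against 7.40 ± 0.13. H2BC3, a histone gene, was 2.12-fold higher, at 7.58 ± 0.05 against 6.50 ± 0.08. SPATA18 was 2.13-fold lower under Comp.4, at 6.00 ± 0.003 against 7.09 ± 0.05, and MDM2 1.84-fold lower, at 8.87 ± 0.08 against 9.75 ± 0.08.

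Under Comp.4, 43 genes were higher than under Comp.2 (12 protein-coding) and 40 lower (31 protein-coding), with 1684 and 1668 at an unadjusted p under 0.05. ULBP1 was higher by log2 1.08 (SE 0.11), the linker histone gene H1-5 by 1.05 (SE 0.11), STC2 by 0.99 (SE 0.08) and the transcription factor gene ETV4 by 0.82 (SE 0.10), as were RN5S122 (1.10), RN5S150 (0.85) and RN5S19 (0.79). The coagulation factor gene F5 had -1.22 (SE 0.11), ABCA12 -1.22 (SE 0.13), PURPL -1.20 (SE 0.09), SULF2 -0.97 (SE 0.08) and EDA2R -0.96 (SE 0.08). WHAMMP1 (-0.89), POLH (-0.85) and the ceramidase gene ACER2 (-0.83) were also lower. Of the 43 higher genes, 22 were small nucleolar or Cajal body RNAs, such as SNORA38 (1.41), SNORA50C (1.37) and SCARNA6 (1.02), and none of that class was lower. RNU-named genes had 4 higher, such as RNU4ATAC (1.04), and 0 lower. The brighter genes of the 2 classes had medians of 0.30 and 0.29.

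Of the 28 p53 targets, 5 were lower under Comp.4 (SPATA18, EDA2R, MDM2, POLH and DDB2, -0.67) and none higher; adjusted over the list alone 22 were lower and 1, PMAIP1 (0.26), higher. The number lower was 21 with a variance trend, 19 among the brighter genes and 0 without any 1 array. The median difference was -0.47 (camera adjusted p = 8.12e-21; adjusted p = 0.133 with an estimated correlation). CDKN1A, at -0.60, did not pass (adjusted p = 0.1001, 95% interval -0.86 to -0.33). Of 25 stress response genes 2, CHAC1 and ASNS, were higher (6 adjusted over the list alone, 8 with a variance trend, 5 of 23 brighter genes), with a median of 0.11, a camera adjusted p of 0.000134 and an adjusted p = 0.177 with an estimated correlation. Of 15 histone genes 2, H2BC3 and H1-5, were higher (9 adjusted over the list alone, 8 with a variance trend, 6 of 11 brighter genes), with a median of 0.35, a camera adjusted p of 1.87e-06 and an adjusted p = 0.175 with an estimated correlation.

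HSPA4L (-0.63), the glucose transporter gene SLC2A3 (-0.67) and TGFB2 (-0.52), which encodes a TGF-β ligand, were each the 1 member of the heat shock, glycolysis and hypoxia, and TGF-β lists to pass, all lower under Comp.4. The 25 NF-κB targets had a median of 0.13, none past, and an adjusted p = 0.221 with an estimated correlation (camera adjusted p = 0.0021). CREBBP had -0.42 (95% interval -0.61 to -0.23, adjusted p = 0.102) and EP300 -0.25 (-0.45 to -0.04, adjusted p = 0.263), and neither passed.

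Both compounds changed 4 genes in the same direction. GDF15 and the antisense RNA IGFL2-AS1 (1.78 under Comp.2 and 1.56 under Comp.4) rose under each, and GUSBP3 and LINC00641 (-0.78 and -0.94) fell under each. Independent lists would share 0.0161 higher and 0.0131 lower genes, and part of the excess over these may come from the shared vehicle arrays. The count was 0 in each of 100 simulations of groups without effects, which sets no scale for lists that hold effects. It was 132 with a variance trend, 63 among the brighter genes, 17 at an adjusted p of 0.10 and 0 without any 1 array. GDF15 differed between the compounds by -0.12 (95% interval -0.30 to 0.06) and GUSBP3 by -0.21 (-0.40 to -0.01), and neither passed. Of the 44 genes called under Comp.2, 42 had the same sign under Comp.4, and 19 differed between the compounds. Of the 33 called under Comp.4, 30 had the same sign under Comp.2, and 14 differed. The shared vehicle arrays raise both same-sign numbers.

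**Figure D4:**
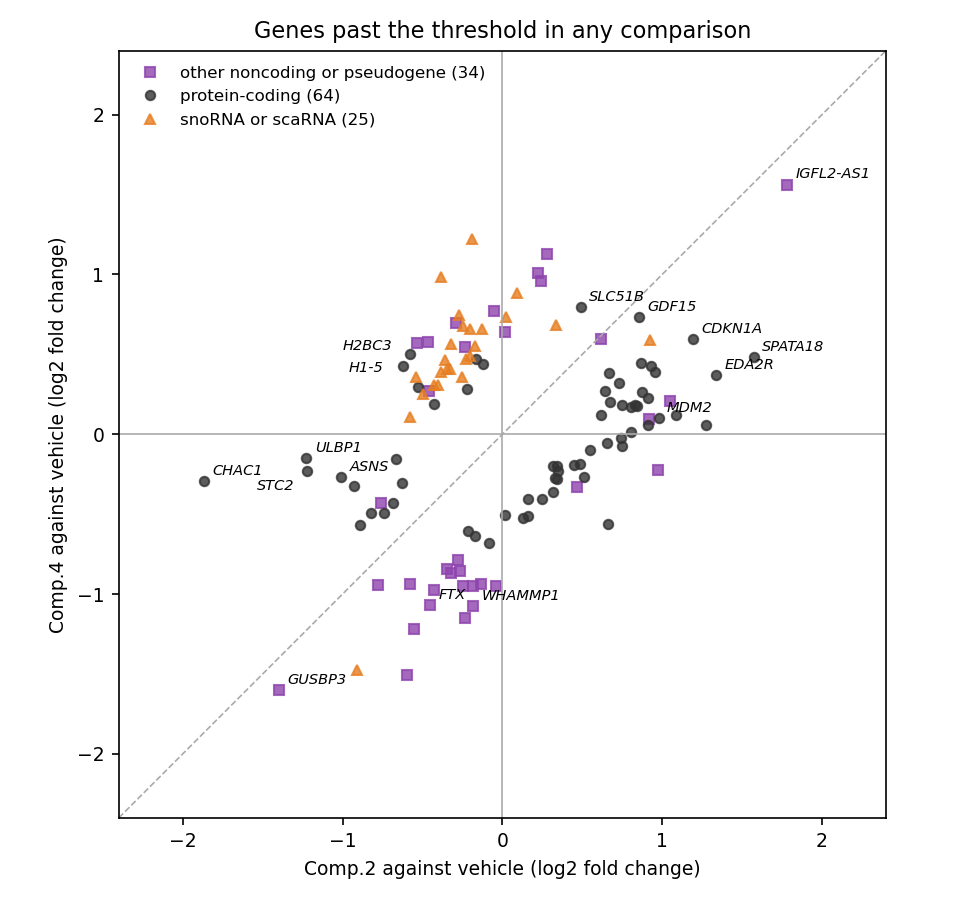
Log2 fold change against vehicle under Comp.2 (x axis) and Comp.4 (y axis) of the genes past the threshold in any of the 3 contrasts (64 protein-coding, 25 small nucleolar or Cajal body, 34 other); the dashed line marks equal change. GUSBP3 and IGFL2-AS1 lie near the line, CHAC1 and SPATA18 nearer the Comp.2 axis, and the small nucleolar and Cajal body RNAs mostly at positive values on the y axis.

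Across the 22395 genes, the fold changes under both compounds had Pearson's r = 0.475 against 0.499 in simulated unchanged groups. They had the same sign in 65.9% against 66.7%, and genes are not independent replicates. Effects of 1 compound alone can lower both measures, so unchanged groups set no scale for them and a shared response is neither shown nor excluded. The covariance was 0.0136, against 0.00562 (0.00538 to 0.00589) in the simulations, a difference of 0.00795. The simulations drew on the moderated rather than the measured variances, so their covariance may be too low and this difference too large. Without any 1 array few or no genes passed between the compounds. All 83 called genes kept their sign, which was fixed in advance, since their arrays did not overlap between groups.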

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

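Both tests of explanations given here were chosen before their results were seen. The 29746 probe sets with several gene symbols or none entered no gene comparison, and a signal appeared among them. Tested by themselves with limma, 1 was higher and 31 were lower under Comp.4 against vehicle (3654 at an unadjusted p under 0.05). Comp.4 against Comp.2 gave 1 higher and 1 lower (2940 unadjusted). Comp.2 against vehicle gave 0 in either direction (2265 unadjusted). What these probe sets measure was not analysed here.

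Among named genes, 18 of the 21 that fell under Comp.4 were not protein-coding: 6 were small RNA loci (RNU4-9P, RNU6-82P, RNU7-55P, MIR590, MIR570 and SCARNA3), and others included the pseudogenes GUSBP3 and WHAMMP1 and the long noncoding RNAs FTX and LINC01347. A signal near the floor of the arrays is argued against for 13 of the 18, which lay above the median level of the genes tested. It stays open for the dimmer ones, RNU4-9P, RNU6-82P, RNU7-55P, MIR590 and WHAMMP1, with Comp.4 means of 3.15 to 4.08. A loss of long noncoding RNA as a class cannot be told apart from falls at single genes: the 80 brighter LINC-named genes had a median of -0.0993, its 95% interval of -0.12 to -0.06 spans the bound of -0.10 set for the test, and all 644 had a median of 0.03. The same 80 genes had -0.07 (-0.10 to -0.02) under Comp.2. An effect of the compound stays open and was not tested apart from processing batches, since scan dates were not used here.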

How the results depend on the processing

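The restriction to protein-coding genes was chosen only after the result was seen. Counts are higher and lower genes for Comp.2 against vehicle, then Comp.4 against vehicle, then Comp.4 against Comp.2. Fitted as reported they were 30 and 14, 12 and 21, and 43 and 40, with 4 genes shared by both compounds. Genes called there kept their sign under each refit that tested them. This was fixed in advance for refits that left the fold changes unaltered or left out 1 array. No named gene or list that passed as reported or in the refit reversed. Those that passed in neither were not checked for a reversal. Replicate numbers 1 and 2 recur in each group, and the labels do not say whether equal numbers share a day. Deviations of same-numbered arrays correlated at 0.03, 0.01 and -0.04, so no pairing was visible in the values. With a replicate block the counts were 9 and 6, 0 and 4, and 0 and 0 (limma; 1609 and 1518 unadjusted in the last), with 1 shared gene and 15, 8 and 9 lists past camera. A fit of only the 2 groups compared gave 9 and 5, 0 and 0, and 0 and 0 (1999 and 1767, then 1448 and 1400 unadjusted), with 0 shared. Leaving out 1 array gave 0 to 9 and 0 to 5, 0 and 0, and 0 to 1 and 0, with 0 shared; the lone array of a group was then assumed to vary like the others. In these fits fewer residual degrees of freedom remain by construction. Without 1 array the covariance ran from 0.0126 to 0.020, and the lists past camera from 12 to 16, 6 to 8 and 7 to 9. Of the named results, 46 no longer passed under the block, 49 in the fit of 2 groups and 49 to 60 without 1 array.

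A variance trend gave 226 and 162, 488 and 738, and 484 and 591 genes, 132 shared, and 15 lists for Comp.4 against vehicle. Brighter genes only gave 154 and 79, 340 and 499, and 324 and 392, with 63 shared. An adjusted p of 0.10, looser by construction, gave 55 and 30, 124 and 185, and 122 and 152, with 17 shared. An unadjusted p of 0.05 with at least 2-fold gave 9 and 7, 5 and 14, and 11 and 6. All probe sets gave 0 and 0, 7 and 92, and 1 and 1 (2303 and 2459 unadjusted in the first), with 0 shared, a covariance of 0.0248 and 11 lists for Comp.4 against vehicle. Protein-coding genes only gave 41 and 21, 0 and 0 (1627 and 1539 unadjusted), and 14 and 33, with 0 shared; the noncoding genes are left out there by construction. Array weights moved the higher genes to 21 under Comp.4 and 28 between the compounds. The mean of probe sets gave 11 lists for Comp.4 against vehicle. With an estimated correlation 0, 0 and 0 lists passed, against 27, 26 and 28 with fry in either direction and 14, 7 and 9 with fry in one direction. For the variance trend, brighter genes, all probe sets, array weights and mean of probe sets the cause was not tested. Robust variance, another quantile normalization, median centring and a cutoff of at least 1.5-fold kept each gene count within 1.5 times. The median of all genes under Comp.4 was 0.02 as deposited, 0.03 after that normalization and 0.02 after centring. Without detection calls, signal over background could be judged only from the brighter genes.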

Other observations

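The tests of 1 Comp.2 array alone and of a weaker form of the Comp.2 response were chosen only after the result was seen, as were the single genes named here. Under Comp.2, rises outside the lists included CD70, a TNF family ligand gene (log2 0.87, SE 0.07), the complement gene C3 (0.83, SE 0.07) and GLIPR1 (0.73, SE 0.07). CBS of the transsulfuration route (-0.66, SE 0.07) and SLC7A1, a cationic amino acid transporter gene (-0.63, SE 0.07), fell. C3 (-0.65) and C5, another complement gene (-0.65), were lower under Comp.4 than under Comp.2. Of 27 genes of extracellular matrix and proteases none passed under Comp.2, and 5 were higher adjusted over the list alone, among them PLAU (0.59) and TIMP2 (0.41). That list had a median of 0.13, with an adjusted p = 0.207 with an estimated correlation, and -0.12 between the compounds (adjusted p = 0.345 with an estimated correlation). Interferon-stimulated genes (median 0.10), cholesterol synthesis genes (0.14), autophagy and lysosome genes (0.06), NF-κB targets (0.06) and 7 mitochondrially encoded transcripts (0.14) also passed camera under Comp.2 with no member past the threshold. With an estimated correlation their adjusted p = 0.207, 0.253, 0.339, 0.207 and 0.239. The heat shock (0.12) and senescence-associated (0.08) lists passed camera too, with an adjusted p = 0.253 and an adjusted p = 0.207 with an estimated correlation.

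Between the compounds, 24 oxidative phosphorylation genes had a median of 0.09, none past (camera adjusted p = 0.00397; adjusted p = 0.221 with an estimated correlation). The acetyltransferase and reader (-0.07), heat shock (-0.11) and TGF-β (-0.11) lists also passed camera there, with an adjusted p = 0.221, 0.543 and 0.221 with an estimated correlation. RPL27, a large ribosomal subunit gene (0.50), and RSL24D1, a gene of its assembly (0.62), were higher under Comp.4, while 0 of 18 listed ribosomal protein genes passed in any contrast. Histone deacetylases, NRF2 targets, aryl hydrocarbon receptor targets, immediate early genes, and epithelial, mesenchymal and alveolar and airway genes passed camera in none of the 3 contrasts, and no member passed.

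The 118 brighter small nucleolar and Cajal body RNA genes had a median of 0.27 under Comp.4 against vehicle, though 5 of them passed as higher and 1, SCARNA3, as lower, and the class was not tested as a set. A single Comp.4 array is argued against, since the lowest median without 1 of them was 0.272. Carry-over of short RNA in the Comp.4 extracts is a candidate explanation: the 86 brighter RNU-named and 5S-named genes, also short, had a median of 0.151, above the bound of 0.136 set for the test, though the 95% interval of 0.03 to 0.26 reaches below it. The 23 RNU-named genes among them had 0.28 (0.03 to 0.33) and the 63 5S-named genes 0.09 (0.003 to 0.24), while all 143 RNU-named genes had 0.01, with 0 higher and 3 lower, none of the 3 among the 23. Between the compounds the same 23 had 0.29 (0.11 to 0.44) and the 63 had 0.08 (0.03 to 0.14). All 143 had 0.02 there, with 4 higher under Comp.4 and 0 lower. An effect of the compound on these RNAs stays open.

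A single Comp.2 array is argued against as the source of the p53 target median, which was at least 0.626 without 1 of them; p53 targets past the threshold went from 10 to 0 without either, and were 23 with a variance trend and 23 among the brighter genes. A hypothesis is that Comp.4 gives a weaker form of the Comp.2 response; in the p53 and stress response lists 7 of 7 members that differed lay farther from vehicle under Comp.2, but all 7 had been called under Comp.2 and 0 under Comp.4, so this count decides nothing. Over the 43 protein-coding genes that differed, 3 tests were run in turn. In the first, 10 (23.3%) lay farther from vehicle under Comp.4, between the bounds of 10% and 25%. In the second, 1, METTL2B, did so in a test of the sum of both fold changes. That test counts opposite movement only where the Comp.4 change is the larger one. In the third, 2, METTL2B and SAP130, of the 3 asked for had a Comp.4 change that a weaker form forbids, past a level corrected for the picking of genes. METTL2B fell under both compounds but further under Comp.4 (-0.68 against -0.08). SAP130 had -0.50 under Comp.4 and 0.02 under Comp.2. Signs were opposite for 26 of the 43, such as H2BC3 (-0.58 under Comp.2, 0.50 under Comp.4) and F5 (0.66 and -0.56), and 22 of the 26 had a Comp.4 change at an unadjusted one-sided p under 0.05, but picking genes by their difference favours opposite signs, so a weaker form and a partly different response cannot be told apart there. Over the 7 long noncoding RNAs and pseudogenes that differed, 5 passed the test of the sum, such as LINC01347 (-1.15 under Comp.4, -0.23 under Comp.2) and WHAMMP1 (-1.07 and -0.18). The short RNAs RPPH1 and VTRNA1-3 were taken out of this set after the result was seen. These 5 lay farther from vehicle under Comp.4, which a weaker form forbids. But all 5 had been called under Comp.4 and 0 under Comp.2, and the set was formed after falls under Comp.4 had been seen. Those falls were also not tested apart from processing batches. A weaker form therefore stays open for these genes, as it does for the p53 and stress response genes.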
